A study of Mus musculus with 6 samples.

How the data were processed

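RNA was measured by sequencing in cerebral cortex of mouse embryos at E18.5, in 3 Control and 3 CAP1-KO libraries. Per the labels' protocols, total RNA was extracted with a phenol-based reagent, treated with DNase, selected for poly(A) and made into strand-specific libraries. Per the submitters' processing notes, the tools STAR and edgeR and the builds GRCm38 and mm10 were named by the authors, with no versions. The read counter, the annotation and any filter are not given in the sources used here. Reads of near-identical genes, such as the actin paralogs, Cfl1 and Cfl2, Myl6 and Myl6b, Rpl21 and Acp1, are therefore uncertain in how they were divided.

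The deposited table held 27179 genes. Per the file headers, the authors deposited log2 normalized counts for each library. It also held, per the file headers, the authors' log2 fold change, mean log2 CPM, F score, p-value and FDR for CAP1-KO against Control. Library columns were assigned to a group from the genotype in their names (FF for flox without Cre, FCRE for flox with Cre). Their numbers did not match the replicate numbers of the labels, so the 6 libraries are called FF1, FF2, FF4, FCRE3, FCRE4 and FCRE5. The labels do not say which libraries shared a litter or a sequencing run, and the replicate wording is the only statement that they are separate biological samples.

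Every library shared 1 lowest log2 value, whose antilog was 0.0584 CPM. After that offset was removed, the values of each library were whole multiples of 1 step, and 100% of them came within 0.01 of a whole read. The recovered depth was 32498524 reads in FF1, 35229159 in FF2, 32443864 in FF4, 36302598 in FCRE3, 35468685 in FCRE4 and 33509504 in FCRE5. A level of 1 CPM corresponded to between 31.2 and 37.3 reads. Intervals and floors (3 reads) cover counting error only, since the reads carry no stated molecular identifiers.

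The planned count test assumed deposited counts. Because the table held log2 values, the fallback written beforehand was used: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(CPM + 1). Genes with a mean of at least 1 CPM over the 6 libraries were tested, which left 13885 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. No covariate or block entered the fit. Groups of 3 against 3 cannot give an exact permutation p below 0.1, so significance rests on limma's moderated variance.

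Before the data were examined, 25 gene lists, the rule for named genes and the alternatives were fixed. Of the lists, 24 could be tested with limma's camera at a preset correlation of 0.01, adjusted over those lists. The mitochondrially encoded genes were not analysed here. An estimated correlation was run beside the preset one. The named genes are Cap1 and Cap2, the 10 largest increases and the 10 largest decreases that passed the threshold with a mean log2(CPM + 1) of at least 1 and no overlap between groups, and up to 4 called members of each list. The MRTF-SRF list always includes Acta2, Actb, Actg1, Srf and Vcl, and the immediate early list Fos and Egr1. A list with no called member gives its 2 members of highest expression. A gene that the rule selects among the increases is not reported here. Other genes named below were chosen after their values were seen.

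Gene symbols were missing for 1170 genes, and 456 of these were filled from RefSeq by gene number. Of all gene numbers, 25275 matched the RefSeq table of GRCm38.p6, which gave coordinates. GC content and transcript length came from GENCODE for 95.3% of tested genes. Replicate pairs were compared by a chi-square per gene on recovered reads, and no pair fell within sampling noise.

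The fit was tested on simulated reads for the 13885 genes of CAP1-KO against Control, drawn with each gene's own dispersion. At a 1.5-fold change 69% of 100 changed genes were recovered, at a 2-fold change 79% of 100 were recovered, and 10 unchanged genes were called. The simulation was first drawn with a smoothed dispersion that was too small, and was then changed to the dispersion of each gene. The list test called the raised list and 1 of 40 unchanged lists. Genes were drawn independently there, so it cannot show how the preset correlation of 0.01 serves lists whose members move together.

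Alternatives fixed beforehand were other size factors, limma-voom on recovered reads, no filter on low values, a pseudocount of 0.1, leaving out each library in turn, an estimated correlation and reduced lists. Added after seeing the data were the deposited log2 values as they stand, scaling to total reads, the Xist level as a covariate, and CAP1-KO against FF4 alone. DESeq2 was not used, since the table held no counts. Lists of hypothalamic, hindbrain and midbrain, septal and basal forebrain, pituitary and sterol synthesis genes were also written after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.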

Results

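Gene expression was measured by poly(A) RNA sequencing in cerebral cortex of mouse embryos (strain C57BL/6N) at E18.5, shortly before birth. CAP1 is an actin-binding protein that takes part in the turnover of actin filaments. The Control group (3 libraries) carried Cap1 alleles flanked by recombination sites, and the CAP1-KO group (3 libraries) carried the same alleles with the Cre recombinase under the Nestin promoter, which is active in neural progenitors. Recovered depth ranged from 32443864 reads in FF4 to 36302598 in FCRE3. The design asks how loss of CAP1 changes gene expression in this tissue, and the series title names target genes of SRF, a transcription factor whose coactivators, the MRTF proteins, are held back by unpolymerised actin. No group carried Cre without the flanked alleles, so effects of the Cre transgene itself cannot be told apart from those of CAP1 loss.

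Cap1 fell in the CAP1-KO libraries and its paralog Cap2 did not pass the test. Cap1 (gene number 12331, GRCm38 chromosome 4, 122859048 to 122886076) measured 184 ± 16.2 CPM in Control and 85.1 ± 2.0 CPM in CAP1-KO (mean ± SD, n = 3 each), so 46.2% of the Control level remained. Its log2 fold change was -1.10 (SE 0.07, limma, Benjamini-Hochberg adjusted p = 0.000283), and every CAP1-KO library lay below every Control library. The labels do not give the deleted exons, so the remaining level is not a measure of intact transcript. Cap2 measured 25.9 ± 0.47 CPM in Control and 24.4 ± 0.76 CPM in CAP1-KO (log2 fold change -0.08, limma adjusted p = 0.390).

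The largest increases in CAP1-KO were mostly in genes of smooth muscle and contractile actin structures, and the decreases were smaller. Of 13885 genes tested, 78 rose and 56 fell (limma, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found in 31 of them, 29 higher and 2 lower, and the 2 lower genes were Dsc3 and Cap1. The largest increases included Ttr (log2 fold change 6.08), Acta2 (4.83), Cnn2 (3.73), Tagln (3.36), Asb2 (2.94), Pcp4l1 (2.47), Actg2 (2.41), Myl9 (2.38) and Tpm2 (2.33). Asb2, a subunit of a ubiquitin ligase that acts on filamins, rose from 0.62 ± 0.33 to 11.3 ± 0.93 CPM (n = 3 each). The largest decreases were Dsc3 (-1.17), a desmosomal cadherin, Cap1 (-1.10), Ankrd63 (-0.93), Acp1 (-0.93), Kcnh3 (-0.89), a potassium channel, Dio2 (-0.84), the deiodinase that activates thyroid hormone, Npas1 (-0.81), Cul9 (-0.80), Flt1 (-0.77) and Nefm (-0.70), the medium neurofilament. All 134 called genes were separated between the groups, as were 25.6% of tested genes, against 10% by chance, and 3194 genes had an unadjusted p under 0.05. The counts depended on single libraries: 36 rose and 6 fell without FF1, 49 and 11 without FF2, 1299 and 2623 without FF4, 62 and 7 without FCRE3, 78 and 175 without FCRE4, and 33 and 3 without FCRE5, while genes changed at least 2-fold numbered 143 without FF4. The increases named in this paragraph kept their call in all 14 alternatives, and of the 10 largest decreases 9 lost it in at least 1.

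MRTF-SRF target genes rose as a group, from strongly raised smooth muscle genes to moderately raised cytoplasmic actins. Of 40 listed genes 36 were tested, 18 rose and 0 fell over all genes (limma), and adjusted over the list alone 22 rose and 2 fell, Itga5 (-0.42) and Thbs1 (-0.38). The median log2 fold change was 0.45 and the mean 0.95 (limma's camera, adjusted p = 7.58e-25, and adjusted p = 0.00596 with an estimated correlation). Cnn2, a calponin that binds actin, rose from 8.42 ± 1.27 to 123 ± 11.2 CPM (adjusted p = 1.78e-05), and Tgfb1i1, a focal adhesion adaptor, from 9.78 ± 0.65 to 46.0 ± 2.55 CPM (limma adjusted p = 2.44e-05). Acta2, smooth muscle actin, rose from 0.80 ± 0.56 to 49.6 ± 13.7 CPM (limma adjusted p = 0.000148). Vcl, which encodes vinculin, rose from 29.1 ± 5.91 to 81.8 ± 2.14 CPM, Fhl2 from 10.4 ± 0.75 to 33.0 ± 1.72 CPM, and Tpm2, a tropomyosin, from 2.68 ± 0.14 to 17.6 ± 1.90 CPM. Actb, cytoplasmic beta-actin, rose from 2569 ± 138 to 4815 ± 247 CPM (log2 fold change 0.91), Actg1 from 406 ± 24.7 to 641 ± 33.4 CPM (0.66) and Srf itself from 64.5 ± 4.67 to 105 ± 6.72 CPM (0.69); of 14 alternatives Actb kept its call in 10 and Actg1 and Srf in 12 each. Actg2 had 3 reads over the Control libraries and 485 over the CAP1-KO libraries, a ratio of 147 after depth (95% exact interval 49.96 to 715). Itga5 and Thbs1 did not pass over all genes, and Zyx (0.44), Ccn1 (0.29), Ccn2 (0.12) and Myh9 (0.04) did not pass either. The list's median in FF4 lay 0.00 above the mean of FF1 and FF2. How reads of the near-identical actin genes were divided is not stated.

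**Figure D1:**
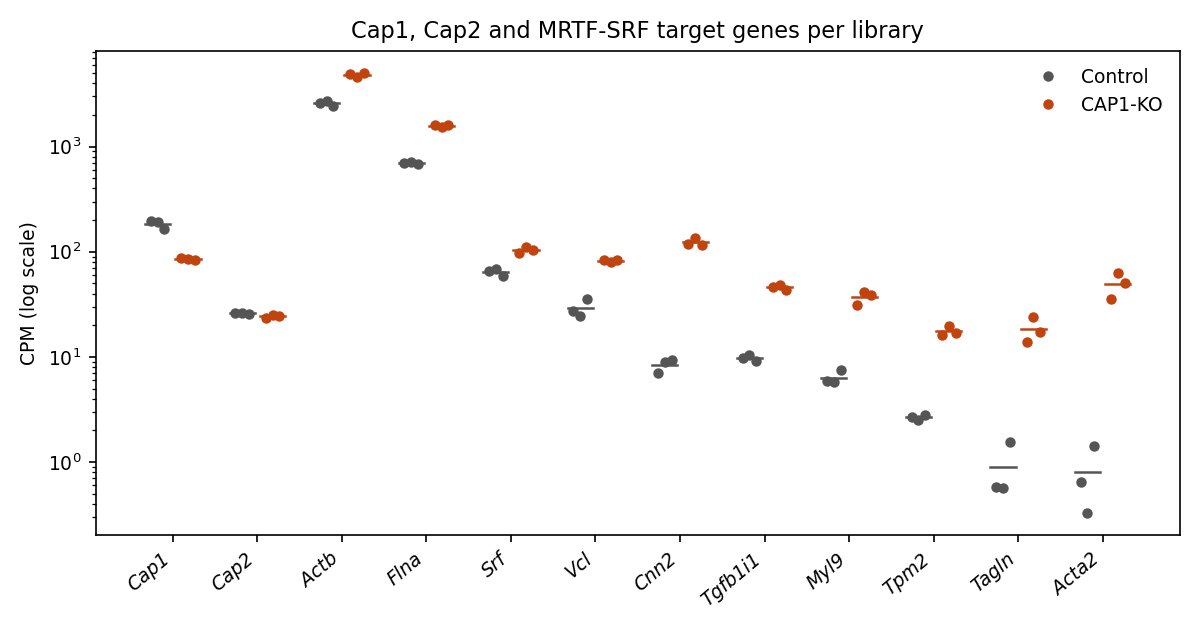
CPM on a log axis for Cap1, Cap2 and 10 MRTF-SRF target genes, with 1 point per library (3 Control, 3 CAP1-KO) and a line at each group mean. Cap1 lies lower in every CAP1-KO library, with means of 184 and 85.1 CPM, and the target genes lie higher, with Cnn2 means of 8.42 and 123 CPM.

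Immediate early genes, which SRF drives with other cofactors, did not move as a group, and a few regulators of actin turnover rose. Among 14 tested immediate early genes 1 rose and 0 fell (limma), and adjusted over the list alone 2 rose (Npas4, Btg2) and 4 fell (Egr3, Nr4a1, Fosl2, Egr1). Npas4, an activity-induced transcription factor, rose from 8.67 ± 4.17 to 33.1 ± 2.04 CPM (log2 fold change 1.90, limma adjusted p = 0.0182), but kept its call in 9 of 14 alternatives (log2 fold change 1.23 to 2.25, adjusted p up to 0.104) and lost it with the Xist level as a covariate and without FF1, FF2, FCRE3 or FCRE5. Fos (0.01) and Egr1 (-0.44, adjusted p = 0.113) did not pass. Fos measured 1.27 CPM in each group, near the 1 CPM filter, where log2(CPM + 1) understates a change. The list's median was -0.13 while its mean was 0.00 (camera adjusted p = 0.498). Of 45 tested actin turnover regulators 3 rose, namely Dstn (200.9 ± 4.19 to 342 ± 14.5 CPM), Cfl1 (910.2 ± 21.5 to 1350.5 ± 24.4 CPM) and Capzb (157 ± 3.10 to 215 ± 5.11 CPM), with 5 higher and 7 lower adjusted over the list alone. Dstn and Cfl1 sever actin filaments and Capzb caps them. Of 14 alternatives Dstn kept its call in all, Capzb in 13 and Cfl1 in 11. That list's median was -0.03 (camera adjusted p = 0.989).

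**Figure D2:**
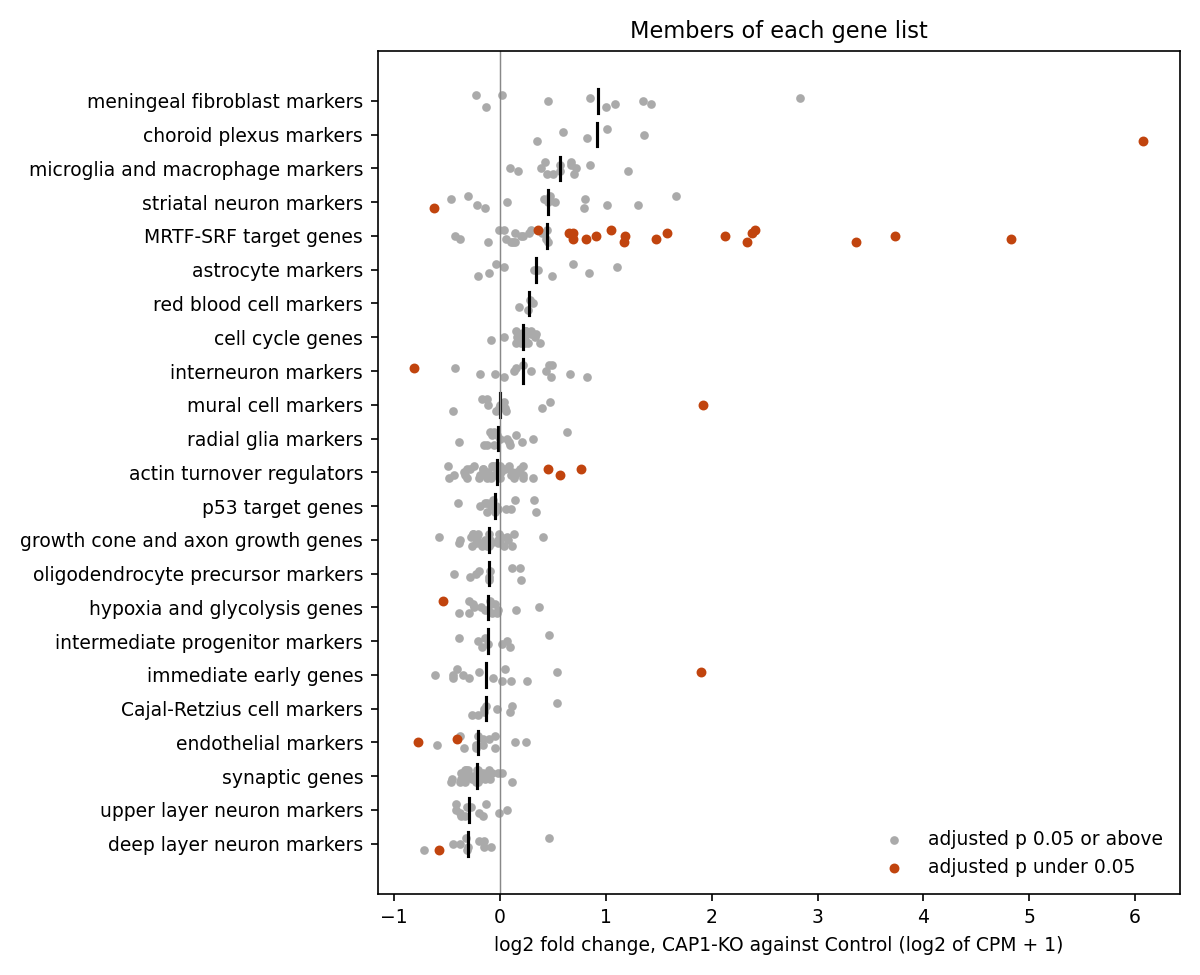
Log2 fold change (CAP1-KO against Control, log2 of CPM + 1) of each tested member of 23 gene lists, with 1 point per gene, coloured where its adjusted p is under 0.05, and a black line at each list's median. The MRTF-SRF list holds 18 coloured genes, all to the right of 0, and its median lies at 0.45.

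Vascular, immune and border-tissue markers moved in different directions. Endothelial markers were lower (15 tested, median -0.21, camera adjusted p = 0.00347, adjusted p = 0.600 with an estimated correlation), and 2 fell, the VEGF receptors Flt1 (18.6 ± 1.80 to 10.5 ± 0.84 CPM) and Kdr (47.3 ± 3.07 to 35.5 ± 2.28 CPM), which kept their calls in 9 and 5 of 14 alternatives (Kdr adjusted p up to 0.353), with 5 lower adjusted over the list alone. Mural cell markers had a median of 0.00 (13 tested, camera adjusted p = 0.498), and 1 of them, Myh11, smooth muscle myosin and itself an SRF target, rose from 0.78 ± 0.17 to 5.81 ± 1.18 CPM, with 2 higher and 1 lower adjusted over the list alone. Microglia and macrophage markers were higher (14 tested, median 0.56, camera adjusted p = 1.59e-08, adjusted p = 0.600 with an estimated correlation), with 0 members past the threshold over all genes and 12 adjusted over the list alone; Csf1r measured 12.4 ± 2.04 and 18.7 ± 1.80 CPM, and all 14 had a positive fold change. Meningeal fibroblast markers had a median of 0.93 (10 tested, 0 called either way, camera adjusted p = 0.00404, adjusted p = 0.703 with an estimated correlation). Against the Control mean that list scored 1.44 in FCRE4 and 1.33 in FCRE5, but 0.026 in FCRE3, below the 0.060 of the Control library FF4. Ptgds, a meningeal gene, measured 1.55 CPM in FCRE3, 42.9 CPM in FCRE4 and 30.1 CPM in FCRE5, against 1.13 ± 0.15 CPM in Control. Choroid plexus markers had a median of 0.91 (6 tested, camera adjusted p = 1.36e-05, adjusted p = 0.600 with an estimated correlation), with 1 higher over all genes and 3 adjusted over the list alone. Ttr, transthyretin of the choroid plexus, measured 0.15 ± 0.16 CPM in Control and 80.5 ± 29.8 CPM in CAP1-KO, and the list's median in FF4 was 0.67 above FF1 and FF2, with a median of 0.41 against FF4 alone, where it kept its call. Red blood cell markers had a median of 0.27 (4 tested, 0 called either way, camera adjusted p = 0.161). That list scored 0.40 in FCRE3, -0.20 in FCRE4 and 0.64 in FCRE5 against the Control mean, and gained a camera call without FCRE4.

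Neuronal lists were lower or mixed, and several moved with the Control library FF4. Synaptic genes were lower (30 tested, median -0.21, camera adjusted p = 4.35e-08, adjusted p = 0.600 with an estimated correlation), with 0 over all genes and 19 lower adjusted over the list alone; Camk2b measured 688 ± 72.1 and 590.5 ± 57.0 CPM. Deep layer neuron markers had a median of -0.31 (12 tested, camera adjusted p = 0.00194, adjusted p = 0.697 with an estimated correlation), with Crym lower (46.9 ± 4.65 to 31.2 ± 2.85 CPM, called in 7 of 14 alternatives) and 5 lower adjusted over the list alone. Upper layer markers had a median of -0.29 (12 tested, camera adjusted p = 0.00404, adjusted p = 0.703 with an estimated correlation), with 0 over all genes and 5 lower adjusted over the list alone. In FF4 the medians of these layer lists lay -0.37 (deep) and -0.42 (upper) from FF1 and FF2, and against FF4 alone they were -0.05 and 0.10. Growth cone genes had a median of -0.10 (30 tested, 0 called either way, camera adjusted p = 0.0325, adjusted p = 0.703 with an estimated correlation), where FF4 lay -0.21 from FF1 and FF2; the median was -0.0089 against FF4 alone, and the call was kept in 9 of 15 alternatives. Striatal neuron markers had a median of 0.46 (15 tested, camera adjusted p = 0.316), of which Ppp1r1b fell (45.4 ± 2.19 to 29.1 ± 2.10 CPM, called in 10 of 14 alternatives), with 2 higher and 2 lower adjusted over the list alone, and FF4 lay 1.19 above FF1 and FF2, with a median of -0.27 against FF4 alone. Interneuron markers had a median of 0.21 (15 tested, camera adjusted p = 0.161), of which Npas1 fell from 21.9 ± 4.32 to 11.9 ± 0.92 CPM (called in 5 of 14 alternatives), with 2 lower adjusted over the list alone, and FF4 lay 0.45 above FF1 and FF2, with a median of -0.034 against FF4 alone. The striatal and interneuron lists each gained a camera call with the Xist covariate and without FF4. Cajal-Retzius markers had a median of -0.13 (9 tested, 0 called either way, camera adjusted p = 0.552).

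**Figure D3:**
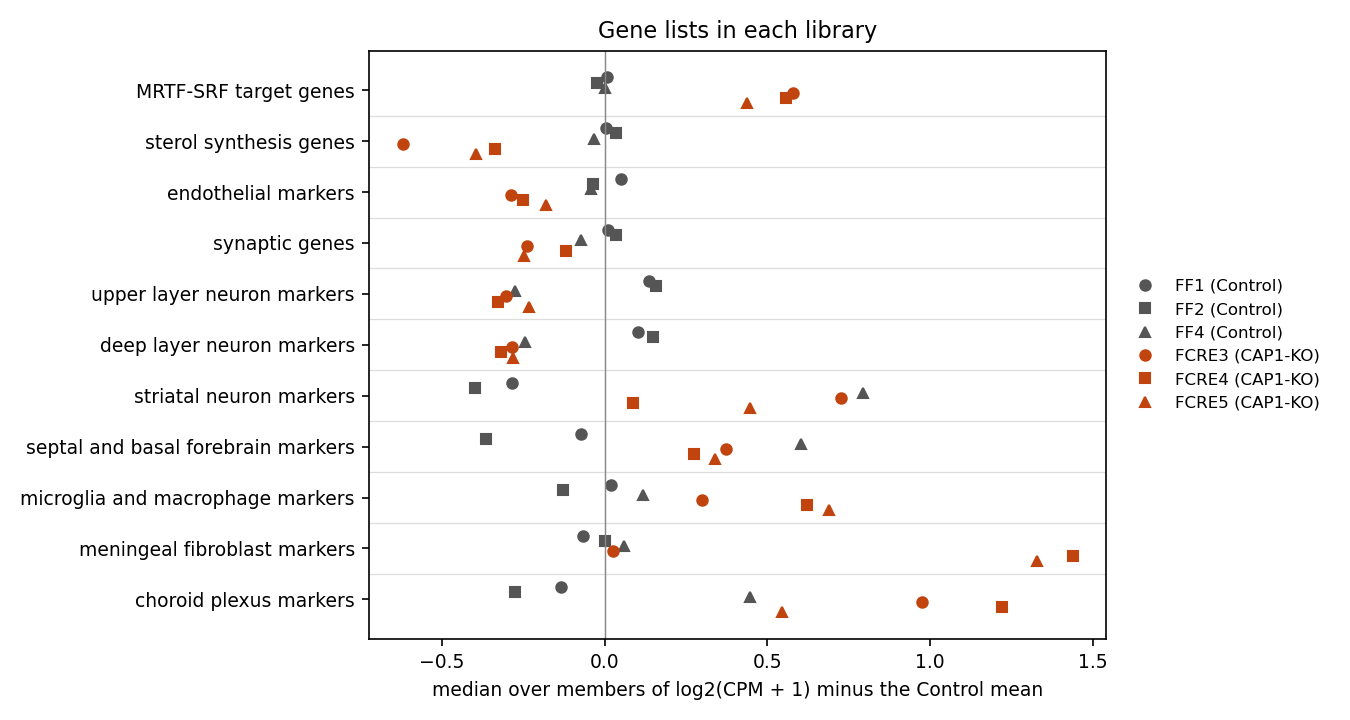
For 11 gene lists, the median over members of log2(CPM + 1) minus the Control mean, with 1 point per library. MRTF-SRF target genes in the CAP1-KO libraries lie between 0.44 and 0.58 and apart from the 3 Control libraries. Striatal and septal markers in FF4 lie at 0.79 and 0.60, above FF1, FF2 and every CAP1-KO library (striatal 0.087 to 0.73, septal 0.28 to 0.37).

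Proliferation genes were higher as a list, and progenitor, astrocyte and oligodendrocyte precursor lists were not called in the main fit. Cell cycle genes had a median of 0.22 (25 tested, camera adjusted p = 6.01e-08, adjusted p = 0.697 with an estimated correlation), with 0 over all genes and 3 higher adjusted over the list alone; Top2a measured 115 ± 8.15 and 135.0 ± 11.3 CPM. That list scored 0.33 in FCRE3 and 0.30 in FCRE5 against the Control mean, but 0.034 in FCRE4, below the 0.12 of the Control library FF1. Radial glia markers had a median of -0.01 and a mean of 0.04 with camera pointing up (16 tested, adjusted p = 0.552, 0 over all genes, 1 higher adjusted over the list alone), and Fabp7 measured 532 ± 47.4 and 555 ± 19.6 CPM. Intermediate progenitor markers had a median of -0.12 and a mean of -0.04, again with camera pointing up (9 tested, adjusted p = 0.819, 0 over all genes, 1 higher adjusted over the list alone). Astrocyte markers had a median of 0.34 (10 tested, 0 called either way, camera adjusted p = 0.0672), and FF4 lay 0.41 above FF1 and FF2, with a median of -0.055 against FF4 alone. The astrocyte list gained a camera call with no filter on low values, with the Xist covariate, without FF4 and without FCRE3. Oligodendrocyte precursor markers had a median of -0.11 (10 tested, 0 called either way, camera adjusted p = 0.346). Their median was -0.21 against FF4 alone, and the list gained a camera call without FCRE4. Hypoxia and glycolysis genes had a median of -0.11 (17 tested, camera adjusted p = 0.0495, adjusted p = 0.703 with an estimated correlation, called in 10 of 15 alternatives), with Ddit4 lower (130 ± 7.72 to 89.4 ± 10.5 CPM, called in 6 of 14 alternatives) both over all genes and as the 1 lower gene adjusted over the list alone. p53 target genes had a median of -0.05 (15 tested, 0 called either way, camera adjusted p = 0.602).

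Embryo sex was not balanced between the groups. Xist, the RNA of the inactive X chromosome, measured 2296 CPM in FF2 and between 2398 and 2653 CPM in the CAP1-KO libraries, against 0.58 CPM in FF1 and 2.05 CPM in FF4. The Y-linked gene Ddx3y measured 58.9 CPM in FF1 and 64.1 CPM in FF4, and 1 read in FF2. The embryo sex list had a median of -3.45 and a mean of -1.25 (6 tested, camera adjusted p = 0.396), with 0 over all genes and 1 higher and 4 lower adjusted over the list alone. With the Xist level as a covariate, 23 genes rose and 3 fell (limma), and 14 MRTF-SRF target genes were among those that rose.

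The authors' deposited table called 221 genes at an FDR under 0.05, 109 higher and 112 lower. Of these, 206 were among the genes tested here, and 128 were called in both with the same sign. The 6 genes called here and not in the authors' deposited table were Rapgefl1, Itgb1, Tspan9, Npas4, Rgs2 and Slc24a3, and for Npas4 that table gives a log2 fold change of 1.93 and an FDR of 0.101.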

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

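The test of the transgene was chosen after its result was seen, and the reading of the pituitary test was changed after its result was seen. Growth hormone, Gh, lay below the level needed for the main test, and was singled out because it had reads in the CAP1-KO libraries alone. It had 73 reads in FCRE3, 59 in FCRE4 and 54 in FCRE5, 186 in all (95% exact interval 160 to 215), and 0 in every Control library. Against a floor of 3 reads over the Control group, its level was at least 56.2-fold higher. Growth hormone sequence carried by the Cre transgene, as Nestin-Cre lines are known to have, stays open as a source: the lowest CAP1-KO library had 54 reads and the highest Control library 0, but Gh was singled out for that same pattern, so these values test nothing. Pituitary tissue in the dissection stays open too. The 7 other pituitary genes had 33.9% as many reads as Gh in the CAP1-KO libraries, 63 against 45 in Control (exact binomial p = 0.149). Control held its 45 reads beside 0 Gh reads, so the 33.9% is no measure of pituitary tissue. These reads were mainly of Tshb (35 against 26) and Fshb (19 against 11). Cga had 3 reads in each group and Pou1f1, Prl and Ghrhr 0 in every library, which gave no sign of added pituitary tissue. The test of the 7 genes had been written to exclude pituitary tissue if their reads were no higher than in Control. They were numerically higher and a missed threshold shows no equality, so it was read as undecided.

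No group held enough libraries (4 or more) for a test of single outlying samples.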

How the results depend on the processing

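The deposited log2 values, scaling to total reads, the Xist covariate and the comparison with FF4 alone were chosen after seeing the data; the other settings were planned. Cap1 stayed lower in all 14 alternatives (log2 fold change -1.18 to -0.95, adjusted p 2.42e-06 to 0.00939), and the MRTF-SRF median stayed between 0.44 and 0.61 in all 16 (adjusted p 6.44e-37 to 0.00596), including 0.44 without its smooth muscle genes. The immediate early median stayed between -0.19 and -0.06 and uncalled. Genes called lower numbered 20 with no filter on low values, where 21292 genes share the adjustment. With the Xist covariate 23 rose and 3 fell, and against FF4 alone 43 rose and 12 fell; both fits leave fewer degrees of freedom, and the lone FF4 is assumed to vary like the CAP1-KO libraries. Leaving out 1 library gave 33 (FCRE5) to 1299 (FF4) genes higher, 3 (FCRE5) to 2623 (FF4) lower, and 22 (FF1) to 143 (FF4) changed at least 2-fold. The other removals gave 36 and 6 (FF1), 49 and 11 (FF2), 62 and 7 (FCRE3), and 78 and 175 (FCRE4). Without FF4, 78 of the 78 higher and 56 of the 56 lower genes remained. The higher share of calls was 58.2% in the main result, 77.3% with no filter, 65.8% scaled to total reads (median of all genes shifted by 0.06), 88.5% with the Xist covariate and 78.2% against FF4 alone. It was lower without FF4 (33.1%) and without FCRE4 (30.8%), where lower calls outnumbered higher ones, and was 81.7% to 91.7% in the other removals. Values that changed sign are given whether or not they were called, except that of 1 gene, which is not reported here. With limma-voom the mural median was -0.00165. Scaled to total reads, Dcx was 0.057, Trp53inp1 0.051, and the medians of actin turnover regulators 0.038, p53 targets 0.013 and radial glia 0.051. With the Xist covariate, Fos was -0.0044, Eif2s3y 0.081, Pdgfra 0.013, and the medians of embryo sex genes 0.048 and radial glia 0.17. Against FF4 alone, Fos was -0.30, Map1b 0.051, Dcx 0.11, Trp53inp1 0.077, Fabp7 -0.077, Kif26b 0.0049, Reln 0.022 and Cacna2d2 -0.31. In that comparison the medians were 0.022 for actin turnover regulators, 0.098 for upper layer, 0.021 for radial glia, 0.23 for intermediate progenitor, -0.034 for interneuron, -0.27 for striatal, 0.0036 for Cajal-Retzius, -0.055 for astrocyte and -0.0105 for mural markers. The septal list, chosen after seeing the data, went from 0.38 (camera adjusted p = 0.0117, p = 0.311 with an estimated correlation) to -0.215 there. Leaving out 1 library gave ranges of -0.14 to 0.17 for Fos, -0.0675 to 0.041 for Dcx, -0.060 to 0.039 for Trp53inp1 and -0.037 to 0.30 for Cacna2d2. For the medians it gave -0.077 to 0.036 for radial glia, -0.34 to 0.040 for intermediate progenitor and -0.049 to 0.039 for mural markers. Of these the radial glia median with the Xist covariate and, against FF4 alone, those of actin turnover regulators, intermediate progenitor and striatal markers passed the threshold with the changed sign, and those of upper layer and septal markers had passed it before. The cause of these changes of sign was not tested. Of 1254 other values 1059 kept direction and side of the threshold, 120 lost the call, 30 gained it and 45 changed sign.

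No paired analysis was possible because the library columns carry no replicate numbers from the labels. The DESeq2 test was not run because the table holds log2 values, and the planned filter at a mean of 1 CPM is the main filter. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split, the 1 split with as many, gave 78 higher, 56 lower and 31 changed at least 2-fold, and no other split called over 1 gene in a direction; the MRTF-SRF median was 0.45 against 0.27. For the immediate early median, 2 of 10 splits were as large, 0.13 against 0.14. Depth limits genes near 1 CPM, where a library holds 31.2 to 37.3 reads.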

Other observations

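The tests of hypothalamic tissue, of a mislabelled FF4, of pericytes, of smooth muscle cells, of tissue outside the cortex for the MRTF-SRF genes and both tests of the sterol genes were chosen after the result was seen, as were the sterol, septal and hypothalamic lists; the septal list was written after some ventral genes had been seen raised in FF4. Sterol synthesis genes were lower in CAP1-KO. Of 23 tested genes of cholesterol synthesis and its control, all 23 had a negative fold change and 9 fell over all genes (limma), Tm7sf2, Acat2, Fdps, Insig1, Hmgcs1, Dhcr7, Lss, Mvk and Stard4, with 21 lower adjusted over the list alone, which is not independent evidence because the list was chosen on these libraries. The median log2 fold change was -0.47 (camera p = 3.07e-17, p = 0.0609 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, measured 1032 ± 6.76 CPM in Control and 728 ± 64.4 CPM in CAP1-KO, and Lss, which closes the sterol rings, 84.6 ± 6.21 and 56.1 ± 6.05 CPM (n = 3 each). The hypothesis that these genes are lower with CAP1 loss, and not through the tissue shared with FF4, predicted a lower median against FF4 alone, and that median was -0.40. But 22 of the 23 members already lay lower in every CAP1-KO library than in every Control library, FF4 included. The prediction was therefore close to met in advance and does not decide between these sources. With the Xist level as a covariate the median was -0.46. The list scored 0.035 in the Xist-expressing Control library FF2 against -0.34 to -0.62 in CAP1-KO. FF2 was thus not lower, but it is 1 library and the list was chosen on the same data, so embryo sex was not tested independently. No single member passed the threshold over all genes in either of those smaller fits, and over the 14 alternatives the 9 genes kept their call in 6 (Mvk) to 11 (Tm7sf2).

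The following genes outside the lists were named after their values were seen. Fblim1, a filamin-binding protein, rose from 32.8 ± 2.13 to 79.7 ± 2.36 CPM, Arpc5, an Arp2/3 subunit, from 208 ± 6.75 to 321 ± 6.40 CPM, and Palld, palladin, from 3.89 ± 0.55 to 8.19 ± 0.61 CPM. The imprinted RNA H19 rose from 32.4 ± 7.83 to 94.2 ± 13.4 CPM. Among vascular genes, Eng fell from 21.2 ± 2.78 to 12.6 ± 0.77 CPM and Apln from 12.6 ± 1.46 to 7.58 ± 0.07 CPM (all limma adjusted p under 0.05). Of the 14 alternatives, Fblim1 and Arpc5 kept their call in all, H19 in 11, Palld in 10, and Eng and Apln in 7 each.

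The Control library FF4 lay apart from FF1 and FF2, towards the CAP1-KO libraries: the first principal component (57.0% of variance) placed FF1 at -22.5, FF2 at -21.8, FF4 at 1.22 and the CAP1-KO libraries between 13.3 and 15.1. A mislabelled knockout is excluded, since Cap1 in FF4 lay 79.0 CPM above the highest CAP1-KO library, whose range was 3.78 CPM, and GC content and transcript length accounted for 3.92% of the variance of the FF4 difference, with 93.4% of genes past 2-fold staying past it once that trend was removed. For the log2 fold change of CAP1-KO against Control they accounted for 8.08%. Septal or basal forebrain tissue in FF4 and the CAP1-KO libraries is a candidate explanation. On log2(CPM + 0.1), 14 of its markers had a median 1.09 above FF1 and FF2 in FF4 and 0.95 in CAP1-KO. Nkx2-1, for example, measured 1.96 and 1.64 CPM in FF1 and FF2, 17.3 CPM in FF4 and 13.7 to 19.0 CPM in CAP1-KO. Hypothalamic markers gave 0.53 in FF4 on log2(CPM + 0.1). On log2(CPM + 1), striatal markers, a list fixed beforehand, lay 1.19 above FF1 and FF2 in FF4 (15 tested). Septal markers gave 0.90 on that scale (12 tested) and hypothalamic markers 0.22 (4 tested). Striatal tissue is therefore a candidate too, and which tissue it may be was not settled. Cortex also expresses some of these markers, Meis2 at 330 ± 18.4 CPM in Control.

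The raised MRTF-SRF genes were set against other sources. A larger share of pericytes is argued against by the median of the 13 mural markers, mostly pericyte genes, 0.0015, which lay below that of the MRTF-SRF list by more than 2 standard errors of their difference (0.187). With the Xist level as a covariate the list's median was 0.59 (camera adjusted p = 8.80e-23), which argues against embryo sex. Against FF4 alone the list's median was 0.60, which argues against the tissue shared with FF4. The first fit rests largely on FF2, the only Control library with Xist near the CAP1-KO level, and the second on FF4. No fit took sex and tissue together. The list scored 0.0087 in FF1, -0.023 in FF2 and 0.00079 in FF4, against 0.44 to 0.58 in the CAP1-KO libraries. The comparison with FF4 does not cover tissue that FF4 lacked. Ttr of the choroid plexus measured 0.33 CPM in FF4 and 47.0 to 104 CPM in CAP1-KO. The meningeal list scored 0.060 in FF4, 0.026 in FCRE3, 1.44 in FCRE4 and 1.33 in FCRE5, while the MRTF-SRF list was highest in FCRE3, at 0.58. Choroid plexus and meningeal tissue were not tested as sources. Over the list as a whole, added smooth muscle cells cannot be told apart from an effect within cells. Outside the list, 18 of their markers, at a median of 3.70 CPM in Control, had a median difference of 0.18 on log2(CPM + 0.1). That lay below the list's median, taken on log2(CPM + 1), by less than 2 standard errors of their difference (0.188). The scales treat low genes differently, so the comparison is not like with like. Both standard errors given here come from resampling genes, not libraries. The test could not have excluded this source, since its rule asked for markers of a higher Control level, and Myh11 is itself an SRF target. For the cytoplasmic actins the values argue against added smooth muscle cells. Actb rose from 2569 to 4815 CPM and Actg1 from 406 to 641 CPM. Both rises exceeded the whole level of Acta2, smooth muscle actin, 49.6 CPM in CAP1-KO, though how reads of actin genes were divided is not stated. An effect of CAP1 loss within cells may account for the pattern but stays a hypothesis, found and tested on the same data. Added smooth muscle cells and an effect of the Cre transgene stand beside it, and the splits of the libraries are too few to exclude chance.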
